A study of Bombyx mori with 6 samples.

How the data were processed

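RNA sequencing libraries from 6 silkworm samples were compared, 3 labelled siNC and 3 labelled siUFBP1. Each group and replicate number was taken from the sample title. Total RNA was made into libraries with a SMARTER mRNA-Seq kit, per the labels' protocols. Reads were processed with fastp, a read trimmer, and HISAT2, a spliced aligner, per the submitters' processing notes. Their versions, the read counter, its handling of strand and of reads shared between genes, and the genome build are not given in the sources used here.

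The deposited table lists 16880 gene models with raw read counts per gene for each library, per the file headers, and these counts were whole numbers with different totals. It also holds FPKM values, which the authors scaled by gene length and library size, per the file headers, and which were used for an alternative. The authors' own comparison, with log2 fold changes, adjusted p-values and calls, is in the same deposited table. Every gene the authors called has an adjusted p of at most 0.0098 and at least a 2-fold change. Product names came from the same table, of which 12588 genes had a name from the NR protein database. Of 6793 silkworm gene numbers in its KEGG column, 6562 were found in a RefSeq gene table, used only for names. No gene had a nucleopolyhedrovirus product, so viral transcripts were not analysed here.

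Totals ran from 25571210 to 53205531 counts per library, so that 3 counts correspond to 0.056 to 0.117 CPM. Intervals and floors cover counting error only. A chi-square test on genes with at least 40 counts in the pair found differences beyond sampling noise in all pairs of replicates (chi-square per degree of freedom 2.68 to 14.4), and each library was kept as its own replicate.

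Genes were filtered with filterByExpr, which left out 6148 gene models holding 0.0479% of the counts. TMM factors were 0.763, 0.767 and 0.746 for siNC and 1.28, 1.30 and 1.38 for siUFBP1. The comparison was edgeR's quasi-likelihood test with group as the only term, and calls were made at a Benjamini-Hochberg adjusted p of 0.05. The common biological coefficient of variation was 3.87%. Standard errors of log2 fold changes were computed as the absolute fold change divided by the square root of the F statistic. For a gene with no count in siNC, the fold was computed against a floor of 3 counts over the group. For 1 to 3 siNC counts the ratio of summed counts is given with a 95% exact binomial interval.

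Before the data were examined, 27 gene lists were fixed as patterns on product names. They cover UFMylation, ER chaperones and foldases, unfolded protein response, ER-associated degradation, ER translocation and glycosylation, apoptosis, autophagy, heat shock proteins, proteasome, ribosomal proteins, respiratory chain, tRNA synthetases, DNA replication and cell cycle, antimicrobial peptides, immune recognition, RNA interference, redox and detoxification, lipid metabolism, amino acid synthesis and transport, retrotransposons, and markers of fat body, hemocytes, silk gland, midgut, muscle, cuticle and ovary. Matches that were plainly other genes by description (59) were removed before statistics were seen. Another 3 lists (testis and sperm flagellum, 30 kDa lipoproteins, female-biased fat body genes) were added after seeing the data. Lists with at least 5 tested members were tested with camera on voom values with a preset correlation of 0.01. KEGG and GO terms of 10 to 500 tested genes were tested with a one-sided Fisher's exact test against tested genes with any term of that kind.

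The named genes were set by a rule fixed with the lists. UFBP1 and BiP are always given. Among called genes with a described product, read here as one described in the NR database, a mean of at least 5 CPM and no overlap between groups, the 10 largest increases and 10 largest decreases are named. With Swiss-Prot descriptions admitted where NR gives none, a trypsin (KWMTBOMO08816) would enter the increases and a major facilitator superfamily gene (KWMTBOMO02505) the decreases. Up to 4 called members of each list with the smallest adjusted p follow, or 2 by mean CPM where none passed, and up to 3 of each enriched term. Not all of these are printed, and those printed do not always follow the order of the rule. The result of 1 gene is not reported here. Genes of the 3 added lists were named after their values were seen.

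Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, no filter, a mean count of at least 10, DESeq2's Wald test, limma-voom, replicate number as a block, leaving out each library, a 2-fold minimum, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean of at least 1. For lists they were camera with an estimated correlation and fry. Library size alone, and the removal of silk gland, testis, storage protein and 30 kDa lipoprotein genes, were added after seeing the data. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15. The tests were tried on simulated counts drawn from a pooled mean per gene over all libraries, the real library sizes and the estimated dispersions. The composition shift between the real groups was not simulated, and genes with few counts were not among those changed. In the simulated siUFBP1 against siNC comparison of 10502 fitted genes, edgeR recovered 84% of 50 genes changed 1.5-fold and 98% of 50 changed 2-fold, and called 14 of 10302 unchanged genes.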

Results

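Gene expression was measured by RNA sequencing in 6 libraries from the silkworm, Bombyx mori. Of these, 3 were labelled as treated with a negative control small interfering RNA (siNC) and 3 with a small interfering RNA against UFBP1 (siUFBP1). UFBP1, also named DDRGK1, is an endoplasmic reticulum (ER) membrane protein of the UFMylation pathway, which attaches the small modifier UFM1 to other proteins. The labels name the fat body, the insect organ of storage and metabolism, as the tissue, and also the cell line BmN, an ovary-derived silkworm line. The protocols describe both larvae on day 3 of instar 5 that received siRNA and then the baculovirus BmNPV, and transfected BmN cells. They name harvests at 24, 48 and 72 h without a time for each library. Statements below about larvae and carried tissue take the libraries as larval fat body, which the labels alone do not settle. The siNC libraries held 28098603, 31760536 and 27100899 counts, and the siUFBP1 libraries 26610837, 25571210 and 53205531.

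The libraries were first described by the gene groups that took most of the counts. Storage proteins and 30 kDa lipoproteins, which the larval fat body makes in bulk, took 74.6% ± 0.26 of the counts in siNC and 48.5% ± 0.766 in siUFBP1 (SD, n = 3 each). Within this group, the female-biased storage protein KWMTBOMO13992 alone went from 12.71% ± 0.239 to 1.669% ± 0.0323 (SD, n = 3 each). Silk gland genes took 0.0518% ± 0.00158 in siNC and 11.2% ± 0.909 in siUFBP1 (SD, n = 3 each). Fibroin heavy chain (KWMTBOMO15365), the main silk protein of the posterior silk gland, alone rose from 0.00816% ± 0.000642 to 9.42% ± 0.884 (SD, n = 3 each). Shares also rose for cuticle genes, by a factor of 5.27, for muscle genes, by 3.06, and for midgut genes, by 2.99. The hemocyte share rose by a factor of 1.22. Genes with at least 1 count numbered 11338 to 11609 in siNC and 13450 to 14477 in siUFBP1. With all libraries drawn down to the smallest total, the ranges were 11329 to 11562 and 13445 to 14217.

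**Figure D1:**
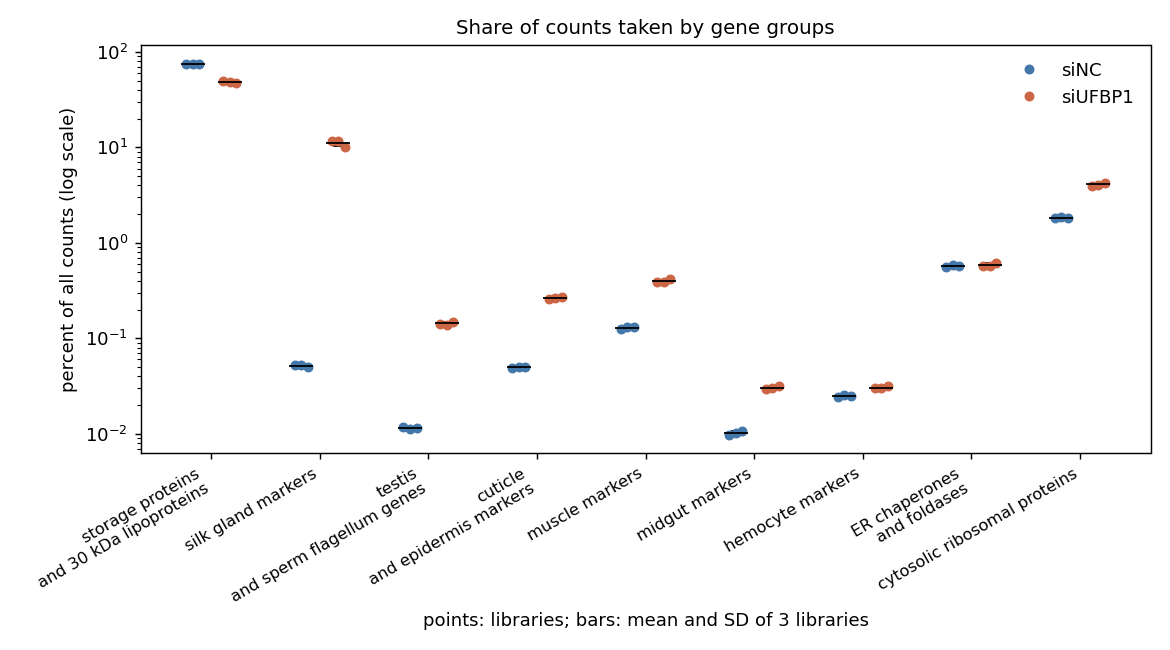
Percent of all counts taken by gene groups (vertical axis, log scale) in each siNC and siUFBP1 library, with points for libraries and bars for the mean and SD of 3 libraries. Silk gland genes went from 0.0518% to 11.2% and storage proteins with 30 kDa lipoproteins from 74.6% to 48.5%, while ER chaperones took 0.57% and 0.588%.

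The first question was whether the UFBP1 transcript was lower in the libraries labelled siUFBP1. In the main scaling it was not. UFBP1 (KWMTBOMO13599) stood at 36.5, 31.1 and 34.2 TMM-normalized CPM, counts scaled to library size and composition, in the siNC libraries and at 32.7, 34.4 and 34.6 in the siUFBP1 libraries. Its log2 fold change, siUFBP1 over siNC, was 0.0043 ± 0.06 (SE), with an adjusted p of 0.951 in edgeR's quasi-likelihood test. The authors' deposited table gives UFBP1 a log2 fold change of -0.0039 with an adjusted p of 0.96. The transcript level therefore gives no check of the labels, and every direction below is that of libraries labelled siUFBP1 against libraries labelled siNC. With upper quartile scaling the log2 fold change was -0.14 (edgeR, adjusted p = 0.0406), and with library size alone, a setting chosen after seeing the data, it was 0.80 (edgeR, adjusted p = 1.55e-10).

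Of 8 tested UFMylation genes, UFBP1 included, 3 were lower, none was higher and 5 did not pass the test, with a median log2 fold change of -0.13. All 8 were higher with library size alone (median 0.67), and with upper quartile scaling 6 were lower (median -0.27). CDK5RAP3 (KWMTBOMO03271), a partner of the UFM1 ligase, had a log2 fold change of -0.44 ± 0.05, and the ligase UFL1 (KWMTBOMO13712) of -0.19 ± 0.05 (SE). With library size alone these 2 values turned to 0.37 and 0.61.

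The second question, from the title of the series, was the level of BiP, the main HSP70 chaperone of the ER lumen. BiP (KWMTBOMO08642) fell from 2639 ± 56.1 CPM in siNC to 1152 ± 8.02 CPM in siUFBP1 (SD, n = 3 each), with no overlap between groups. This was a 2.29-fold decrease, with a log2 fold change of -1.20 ± 0.03 (SE) and an adjusted p of 3.39e-17 in edgeR's quasi-likelihood test. With library size alone the log2 fold change was -0.40 (edgeR, adjusted p = 2.64e-09). The middle quartiles of the fat body markers, a list fixed before the data were seen, ran from -1.13 to -0.19 around a median of -0.68. Those of the 30 kDa lipoproteins, a list added after seeing the data with 19 of 19 tested members lower, ran from -1.31 to -0.95 around a median of -1.08 (-0.28 with library size alone). The fat body genes and silk gland genes whose shares of counts shifted did so in the same 3 libraries.

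Of 19 tested ER chaperones and foldases, 14 were lower, 4 were higher and 1 did not pass, and 3 were lower and 3 higher by at least 2-fold. With library size alone 10 were higher and 5 lower. Endoplasmin (KWMTBOMO12844), the ER form of HSP90, fell 3.01-fold, with a log2 fold change of -1.59 ± 0.04. The lectin chaperone calreticulin (KWMTBOMO12902) fell by 0.92 ± 0.03 and hypoxia up-regulated protein 1 (KWMTBOMO11064) by 0.97 ± 0.04 on the log2 scale (SE). The list median was -0.56 (0.23 with library size alone). The list stood lower than other genes in camera with a preset correlation (adjusted p = 0.000314), and not with an estimated correlation (adjusted p = 0.166).

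Genes of ER translocation and glycosylation, which bring new proteins into the ER, gave 23 lower, none higher and 6 not passing of 29 tested. The delta subunit of the translocon-associated protein (KWMTBOMO14815) had a log2 fold change of -1.33 ± 0.03 and the oligosaccharyltransferase subunit STT3A (KWMTBOMO09289) of -1.05 ± 0.04 (SE). The median was -0.33 (0.47 with library size alone). Library size alone turned the counts to 23 higher and 4 lower, and upper quartile scaling gave 28 lower and none higher. Camera gave an adjusted p of 8.97e-09 with the preset correlation and an adjusted p of 0.0309 with an estimated correlation. The call ended with library size alone (camera, adjusted p = 0.611).

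Among the 6 sensors and transcription factors of the unfolded protein response, 3 were lower and 3 higher in the main scaling. Upper quartile scaling gave 3 lower and none higher, and library size alone 5 higher and none lower. The bZIP factor named activating transcription factor of chaperone (KWMTBOMO06713) had a log2 fold change of -0.59 ± 0.03 (0.20 with library size alone) and the ER stress sensor IRE1 (KWMTBOMO10231) of -1.02 ± 0.12 (SE). The eIF2-alpha kinase (KWMTBOMO04082) was at -0.30 ± 0.07 (0.50 with library size alone). Tribbles homolog 2 (KWMTBOMO01751) was at 0.28 ± 0.08 (SE). The change of IRE1 did not pass with library size alone, nor did that of tribbles homolog 2 with upper quartile scaling.

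Of 17 tested genes of ER-associated degradation, which removes misfolded proteins, 7 were lower, 4 were higher and 6 did not pass. Upper quartile scaling gave 10 lower and 4 higher, and library size alone 1 lower and 11 higher. The ubiquitin-conjugating enzyme E2 G2 (KWMTBOMO00520) fell by 1.73 ± 0.05, the ATPase TER94 (KWMTBOMO11666) by 0.80 ± 0.04 and the mannosidase-like protein EDEM3 (KWMTBOMO00315) by 0.83 ± 0.07 on the log2 scale, whereas derlin-2 (KWMTBOMO04541) rose by 0.72 ± 0.05 (SE). Neither TER94 nor EDEM3 passed with library size alone. Camera placed neither the UFMylation list (adjusted p = 0.22), nor the unfolded protein response list (adjusted p = 0.394), nor ER-associated degradation (adjusted p = 0.234) apart from other genes.

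**Figure D2:**
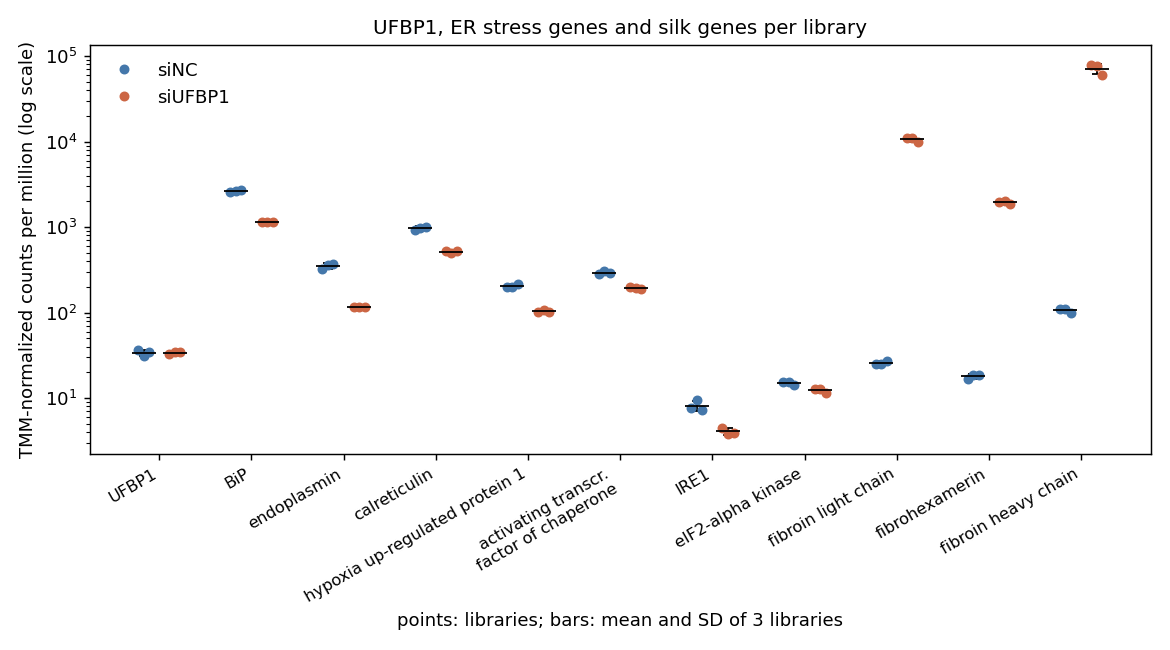
TMM-normalized CPM (vertical axis, log scale) of UFBP1, ER chaperones, stress sensors and silk genes in each library, with points for libraries and bars for the mean and SD of 3 libraries. UFBP1 was near 34.0 in both groups, BiP went from 2639 to 1152 and fibroin light chain from 25.6 to 10680.

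Apoptosis genes, which the series title also names, went both ways in the main scaling. Of 40 tested, 15 were higher, 14 were lower and 11 did not pass, and the list did not stand apart (camera, adjusted p = 0.942). For this list 32 were higher and none lower with library size alone, with a median of 0.91 against 0.11 in the main scaling. The largest change among its examples was in a gene described as apoptosis-inducing factor (KWMTBOMO08168), which rose 51.2-fold from 0.559 ± 0.0806 to 29.04 ± 1.65 CPM (SD, n = 3 each). Its siNC counts were only 10, 15 and 12, and its GO annotation includes motor activity, so its role in apoptosis is uncertain. Daxx (KWMTBOMO01130) rose 1.99-fold, the BCL2 partner BNIP3 (KWMTBOMO06110) 4.27-fold and programmed cell death protein 2-like (KWMTBOMO03413) 3.00-fold. These 4 examples have the smallest adjusted p of the list (edgeR) and all rose, so they do not represent the 14 lower members. Autophagy genes gave 17 higher, 3 lower and 7 not passing of 27, with Atg8 (KWMTBOMO06633), the autophagosome membrane protein, 2.23-fold higher and a WD repeat phosphoinositide-binding protein (KWMTBOMO10639) 2.34-fold higher. This list did not pass camera (adjusted p = 0.146), and passed with no count filter (camera, adjusted p = 0.0452).

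Across all genes, 10732 were tested, 4291 were higher and 3045 lower in siUFBP1, and 3396 did not pass. A change of at least 2-fold was found for 2436 higher and 548 lower genes. Upper quartile scaling turned the balance to 3640 higher and 3807 lower. With library size alone the split was 8607 higher and 452 lower, and with limma-trend on the authors' FPKM values, which also changes the test, the filter and the scaling, it was 6628 and 406. Among the 27 fixed lists, 13 had more higher than lower genes and 13 more lower than higher in the main scaling, against 10 and 16 with upper quartile scaling. In 26 of them more genes were higher with library size alone, and only the fat body markers had more lower ones (10 lower, 7 higher). The median log2 fold change of all tested genes was 0.11 in the main scaling and lay 0.81 higher with library size alone and 0.14 lower with upper quartile scaling. Groups did not overlap for 7637 genes, 71.2% of those tested, where chance alone gives 10%. Of the higher genes, 681 had no count in any siNC library. The labels name no separate cultures or animals behind the replicates, so p-values measure only the spread between these libraries, which may be technical.

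Among the 10 largest increases with a product described in the NR protein database, 5 were tubulin genes. Each of the 10 had 0 counts in all 3 siNC libraries, so its fold is a lower bound against a floor of 3 counts over the group. A beta-tubulin (KWMTBOMO09319) reached 2011 ± 41.1 CPM in siUFBP1 (SD, n = 3), at least 44200-fold higher, and a neighbour in the table (KWMTBOMO09320) was at least 30300-fold higher. The tubulins KWMTBOMO00076, KWMTBOMO13329 and KWMTBOMO16009 were at least 8750-fold, 8060-fold and 4930-fold higher. Not every tubulin rose, since a beta-1 chain-like copy (KWMTBOMO12286) fell 2.51-fold, from 3191 ± 137 to 1273 ± 9.2 CPM (SD, n = 3 each). The KBP homolog (KWMTBOMO00053) was at least 2830-fold higher, a protease described as mast cell protease 3 (KWMTBOMO07954) at least 2260-fold, and an EF-hand family member B gene (KWMTBOMO11536) at least 1760-fold. Testis-specific kinase 2 (KWMTBOMO15186) and the tubulin polyglutamylase TTLL1 (KWMTBOMO10366) were at least 1970-fold and 1830-fold higher. Tubulins, 30 kDa lipoproteins and storage proteins are families of similar genes, and how reads shared between copies were counted is not given in the sources used here.

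The 10 largest decreases with a product described there included transporters and storage proteins. The carcinine transporter (KWMTBOMO05330) fell 22.9-fold, a phosphate cotransporter (KWMTBOMO04235) 17.7-fold, a sulfate anion transporter (KWMTBOMO10634) 15.2-fold and synaptic vesicle glycoprotein 2B (KWMTBOMO12490) 13.4-fold. Sex-specific storage-protein 1 (KWMTBOMO13992), a female-biased storage protein of the larval fat body, fell 13.2-fold from 167600 ± 4070 to 12670 ± 321 CPM (SD, n = 3 each). Inorganic phosphate transporter 1 (KWMTBOMO04237) fell 11.8-fold, the trehalose transporter Tret1 (KWMTBOMO11792) 9.98-fold and a nitric oxide synthase-like gene (KWMTBOMO05879) 9.05-fold. A juvenile hormone-suppressible storage protein (KWMTBOMO01258) fell 8.56-fold and calexcitin-2 (KWMTBOMO01582) 8.30-fold.

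Marker lists of other tissues moved apart. Of 6 tested silk gland genes, 5 were higher and 1 did not pass. Fibroin heavy chain rose 666-fold, fibroin light chain (KWMTBOMO08464) 417-fold, seroin 2 (KWMTBOMO02540) 170-fold and fibrohexamerin (KWMTBOMO01001) 109-fold. Of 46 cuticle genes, 40 were higher and none lower, with cuticular proteins RR-1 motif 23 (KWMTBOMO13165) and motif 3 (KWMTBOMO04385) 7.38-fold and 4.89-fold higher. Of 29 muscle genes, 18 were higher and 7 lower, with troponin I (KWMTBOMO08034) 3.51-fold and paramyosin (KWMTBOMO00171) 3.21-fold higher. Of 23 midgut genes, 17 were higher and 4 lower, with a trypsin (KWMTBOMO08816) at least 1860-fold higher over 0 counts in siNC and a carboxypeptidase B (KWMTBOMO10343) 60.4-fold higher. The midgut median was 4.09, or 3.72 with genes at 0 in siNC set to their bound. Camera placed silk gland (adjusted p = 0.00262), cuticle (8.97e-09), muscle (0.00693) and midgut (0.0278) genes above the rest. With an estimated correlation the cuticle list kept its call (adjusted p = 0.0309), and the other 3 lists did not (adjusted p = 0.249 each). The midgut call also ended with no count filter (camera, adjusted p = 0.206) and with library size alone (camera, adjusted p = 0.445).

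Fat body markers gave 16 lower, 1 higher and 7 not passing of 24, with a median log2 fold change of -0.68 (0.12 with library size alone). Camera gave an adjusted p of 1.36e-06, and an adjusted p of 0.157 with an estimated correlation. Of 30 hemocyte genes, 19 were lower and 6 higher, with integrin alpha-PS2 (KWMTBOMO05421) at -0.98 ± 0.04 and a class B scavenger receptor (KWMTBOMO14155) at -2.44 ± 0.11 (SE). Another class B scavenger receptor (KWMTBOMO03156) went the other way, at 1.84 ± 0.09 (SE). The median of the hemocyte genes was -0.59 (0.21 with library size alone), with a camera adjusted p of 0.00693, and an adjusted p of 0.198 with an estimated correlation. Of 9 ovary and germ line genes, 6 were lower and 1 higher (camera, adjusted p = 0.1). The counts turned to 4 higher and 1 lower with library size alone, where the list passed on the lower side relative to other genes (camera, adjusted p = 0.0317). Among these genes vasa-like (KWMTBOMO11560) had a log2 fold change of -0.31 ± 0.04 (0.49 with library size alone) and an early chorion gene (KWMTBOMO00739) of -0.84 ± 0.13 (SE), which did not pass with library size alone.

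Most cytosolic ribosomal proteins rose, with 66 higher, 3 lower and 5 not passing of 74 and a median of 0.39. RpL14 (KWMTBOMO06721) rose 1.62-fold and RpL5 (KWMTBOMO08797) 1.55-fold. Camera gave an adjusted p of 2.37e-11, and an adjusted p of 0.102 with an estimated correlation. Aminoacyl-tRNA synthetases gave 14 lower and 2 higher of 24, with a median of -0.44 (0.36 with library size alone). The 2 higher members, glycine (KWMTBOMO08652) and alanine (KWMTBOMO01927) tRNA ligase, rose 2.28-fold and 2.14-fold, and these amino acids are the most frequent in fibroin. The list passed camera (adjusted p = 0.00157), not with an estimated correlation (adjusted p = 0.198) nor with library size alone (adjusted p = 0.0661).

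Other fixed lists did not pass camera in the main scaling. Heat shock proteins outside the ER gave 30 higher and 12 lower of 51 (adjusted p = 0.0542), with a small heat shock protein (KWMTBOMO16001) 9.95-fold and an HSP68-like gene (KWMTBOMO16088) 4.69-fold higher. They passed without the count filter (camera, adjusted p = 0.0111), with library size alone (7.32e-06) and without siUFBP1 replicate 1 (0.0471). Of 83 respiratory chain genes, 36 were higher and 20 lower (camera, adjusted p = 0.234). Their median log2 fold change was 0.07 and their mean 2.57, and 14 of them had no count in siNC. Upper quartile scaling gave 31 higher and 34 lower. All 83 were higher with library size alone, and the list passed (camera, adjusted p = 1.92e-05). A Rieske subunit (KWMTBOMO00410) with 2 siNC counts had a count ratio of 707 (95% counting interval 196 to 5840), and a succinate dehydrogenase subunit (KWMTBOMO08409) was at least 575-fold higher. Proteasome genes gave 8 higher and 14 lower of 36 (36 higher with library size alone, and 5 higher and 23 lower with upper quartile scaling; the list passed on the higher side with library size alone, camera, adjusted p = 0.0021), with a beta type-2 copy (KWMTBOMO02409) at least 232-fold higher and regulatory subunit 3 (KWMTBOMO02025) 1.37-fold higher. DNA replication and cell cycle genes gave 32 higher and 11 lower of 67, with cyclin B (KWMTBOMO02674) 4.52-fold and origin recognition complex subunit 3 (KWMTBOMO13134) 1.79-fold higher.

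Defence and metabolic lists held genes of both directions in the main scaling. With library size alone the higher and lower counts became 10 and 1 for antimicrobial peptides, 32 and 2 for immune genes, 8 and 1 for RNA interference, 91 and 9 for redox genes, 126 and 13 for lipid metabolism and 34 and 7 for amino acid genes. Antimicrobial peptide genes gave 6 higher and 8 lower of 15, with a lysozyme-like gene (KWMTBOMO16273) at -1.12 ± 0.04 and lysozyme (KWMTBOMO01155) at -0.70 ± 0.03 (SE; 0.10 with library size alone). Immune recognition and signalling genes gave 14 higher and 16 lower of 44, with beta-1,3-glucan recognition protein 3 (KWMTBOMO06449) 3.18-fold higher and a peptidoglycan recognition protein (KWMTBOMO04838) at -1.17 ± 0.05 (SE). RNA interference genes gave 1 higher and 4 lower of 13, with loquacious (KWMTBOMO04413) at -0.40 ± 0.06 and sid-1-related gene 3 (KWMTBOMO07556) at -0.75 ± 0.11 (SE), which turned to 0.40 and 0.06 with library size alone. Redox and detoxification genes gave 45 higher and 46 lower of 120, with a UDP-glucosyltransferase (KWMTBOMO04051) 4.16-fold higher and a CYP339A1 copy (KWMTBOMO11024) at least 535-fold higher. Lipid metabolism genes gave 61 higher and 58 lower of 156, with lipase 3-like (KWMTBOMO10006) at -1.79 ± 0.03 (SE). Phospholipase A2 (KWMTBOMO09762) was 369-fold higher over siNC counts of 0, 0 and 6. Amino acid synthesis and transport genes gave 23 higher and 16 lower of 47. Glutamine synthetase 1 (KWMTBOMO05463), with 2 siNC counts, had a count ratio of 2030 (95% counting interval 563 to 16800), and delta-1-pyrroline-5-carboxylate dehydrogenase (KWMTBOMO08578) rose 5.55-fold. Of 299 retrotransposon and virus-like genes, 77 were higher and 49 lower (65 and 63 with upper quartile scaling, 176 and 8 with library size alone), with KWMTBOMO06644 10.3-fold higher and KWMTBOMO12285 at -1.14 ± 0.03 (SE). The median and the mean of a list differed in sign for the proteasome (-0.09 and 0.29), antimicrobial peptides (-0.36 and 0.13), immune genes (-0.11 and 0.18) and redox genes (-0.01 and 0.87). Camera also placed lipid metabolism and retrotransposon genes on the lower side, although their means were 1.01 and 0.34, and the retrotransposon list passed there with library size alone (camera, adjusted p = 6.97e-05). Adjusted over the list alone, counts differed for 4 lists, with 47 lower redox genes, 7 higher hemocyte genes, 41 higher and 1 lower cuticle genes, and 72 higher and 42 lower retrotransposon genes.

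Annotation terms were enriched mostly among lower genes, with 29 KEGG pathways of 114 tested and 17 GO terms of 189 tested. Among higher genes, 2 KEGG pathways and 6 GO terms passed (one-sided Fisher's exact test, adjusted over each kind and direction). Among genes changed at least 2-fold the balance turned, with 16 of 29 terms among higher genes and 13 among lower genes, and neither the ribosome nor the breakdown of valine, leucine and isoleucine passed. Breakdown of valine, leucine and isoleucine had 39 of 42 genes lower, where 16.6 would follow from all annotated genes (adjusted p = 3.65e-11, Fisher's exact test), with aldehyde dehydrogenase X (KWMTBOMO07147) at -1.53 ± 0.03 and a methylmalonate-semialdehyde dehydrogenase (KWMTBOMO10946) at -1.25 ± 0.03 (SE). Fatty acid degradation had 31 of 39 genes lower (adjusted p = 1.87e-05, Fisher's exact test), among them an aldehyde dehydrogenase of family 7 (KWMTBOMO05535) at -1.12 ± 0.03 (SE). The lower pathways share genes, so their number does not count separate results. Both KWMTBOMO07147 and KWMTBOMO05535 were leading members of these 2 pathways and also of tryptophan metabolism and lysine degradation. The ribosome pathway had 71 of 116 genes higher (adjusted p = 1.9e-09, Fisher's exact test). The longevity regulating pathway had 30 of 57 higher (adjusted p = 0.038, Fisher's exact test), and its leading members were small heat shock proteins and HSP70 relatives. One of them, an alpha-crystallin gene (KWMTBOMO03131) with 1 siNC count, had a count ratio of 3710 (95% counting interval 666 to 147000).

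The authors' deposited table calls 1902 genes up and 452 down among 9321 tested. All 1902 and all 452 were also higher and lower here. The authors' deposited table gives BiP a log2 fold change of -1.20.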

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

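Of 1302 values for 93 of the genes named besides UFBP1 and BiP, 1281 kept their direction and their side of the threshold. Library size alone, chosen after seeing the data, turned CDK5RAP3 (KWMTBOMO03271) to 0.37, UFL1 (KWMTBOMO13712) to 0.61, activating transcription factor of chaperone (KWMTBOMO06713) to 0.20, the eIF2-alpha kinase (KWMTBOMO04082) to 0.50, lysozyme (KWMTBOMO01155) to 0.10, loquacious (KWMTBOMO04413) to 0.40, sid-1-related gene 3 (KWMTBOMO07556) to 0.06, vasa-like (KWMTBOMO11560) to 0.49 and vitellogenin (KWMTBOMO16492) to 0.68. It put UFBP1 at 0.80, gave 8607 higher and 452 lower genes and 23 enriched terms, and turned the list tests of UFMylation (adjusted p = 0.534), unfolded protein response (0.773), proteasome (0.0021) and amino acid synthesis (0.449, camera). The setting itself moves every gene, since it drops the composition factor. Upper quartile scaling put UFBP1 at -0.14 and an axoneme-associated gene (KWMTBOMO13609) at -0.0081. It moved the median of all tested genes by -0.14, so these moves follow the shift of all genes. A 2-fold minimum left 2436 higher and 548 lower genes and 29 terms, by its construction. Limma-trend on FPKM values with pseudocounts of 1 and 0.1 gave 6628 and 6604 higher and 406 lower genes in both. Gene lengths implied by counts, totals and FPKM had median ratios of 0.9878 to 1.009 to those of siNC replicate 1. The FPKM values therefore lack the composition factor, as with library size alone. The parts played by the test and the filter were not tested. With all tested genes as background 96 terms were enriched against 54, and the cause was not tested. Of 10 called lists, 2 were called with an estimated correlation and fry called 27, with retrotransposon genes on the higher side (adjusted p = 0.0428). The estimated correlations were above the preset 0.01 for the 8 lists that lost their call, and fry does not compare a list with other genes. For the 2 lists that kept their call the estimates were below 0.01, at -0.0199 (ER translocation) and -0.00435 (cuticle). Their camera adjusted p still rose from 8.97e-09 to 0.0309 each, so a higher correlation is not the only cause of weaker list tests. Without silk gland, testis, storage protein and 30 kDa lipoprotein genes, a setting chosen after seeing the data, 4133 genes were higher and 2973 lower, and BiP was at -1.19.

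Leaving out 1 library gave 3983 to 4255 higher and 2789 to 2919 lower genes, 10 to 11 lists, 49 to 56 terms, BiP from -1.21 to -1.18 and UFBP1 from -0.06 to 0.06. Vitellogenin genes near the floor ranged from -0.38 to 0.21 (KWMTBOMO16492) and from -0.13 to 1.41 (KWMTBOMO16057), and the apoptosis list, not called in any, had adjusted p values from 0.883 to 0.998 (camera). Replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at 0.024, -0.019 and 0.018, and not every library correlated best with its own number. With replicate number as a block, 4019 genes were higher and 2824 lower, UFBP1 was at 0.0018, BiP at -1.20, 10 lists and 52 terms were called, and the apoptosis list turned sides without a call (camera, adjusted p = 0.881). The block shared 4010 higher and 2819 lower calls with the fit without it. At these depths simulated changes of 1.5-fold were found for 84% of genes, so smaller changes may be missed. Changes in genes with few counts, and groups of unlike composition, were not simulated, so their rates are not known.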

Other observations

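The tests of explanations in this part, with the splits, the 3 added lists and library size alone, were chosen after the results were seen. Sperm tail genes formed a group outside the fixed lists. Of 107 tested genes in a list of testis and flagellum names drawn up after seeing the top genes, 99 were higher, 3 lower and 5 did not pass. Their share of counts went from 0.0115% ± 0.000257 to 0.143% ± 0.00621 (SD, n = 3 each). Of these genes, 54 had no count in siNC, and the median log2 fold change was 5.36 with those genes at their bound. Ciliary dynein intermediate chain 3 (KWMTBOMO01610), a motor of the sperm tail, was at least 1300-fold higher over 0 counts in siNC. The axoneme-associated gene mst101(2) (KWMTBOMO13609), present in both groups, was only 1.10-fold higher. In the same libraries sex-specific storage-protein 1 (KWMTBOMO13992) went from 12.7% ± 0.239 to 1.67% ± 0.0323 of the counts, while both vitellogenin genes (KWMTBOMO16492 and KWMTBOMO16057) averaged under 0.4 CPM in both groups. Within the 30 kDa lipoproteins, the 4 most abundant fell by 1.06 to 1.37 on the log2 scale, led by KWMTBOMO11909.

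The silk gland and testis lists each took a larger share of the counts in all 3 siUFBP1 libraries than in the siNC libraries. Depth is argued against, since the lowest siUFBP1 library held 13273 detected genes with all libraries drawn down to the smallest effective size, their total times the TMM factor, and the highest siNC library 11571. A smaller fat body share that lifts all other tissues alike is argued against too, because the silk gland and hemocyte factors differed 176-fold. RNA carried in from posterior silk gland and testis stays open, and the rise of 83.3% of the tested silk gland genes decides nothing because it restates the pattern. Changed transcription after the siRNA cannot be told apart from carried tissue, because both fall on the same 3 libraries and UFBP1 itself moved by 0.0043. A difference in the sex of the larvae between the groups stays open too, for the testis genes and for other calls, and was not tested. The share of the female-biased storage protein KWMTBOMO13992 fell from 12.71% to 1.669%. The shares of the storage proteins KWMTBOMO01262 (10.03% to 8.252%) and KWMTBOMO01263 (10.48% to 6.704%) fell less. In TMM-normalized CPM, KWMTBOMO13992 fell 13.2-fold, KWMTBOMO01258 8.56-fold and KWMTBOMO01263 2.71-fold. Of 107 tested testis genes, 99 were higher.

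UFBP1 was not called lower in the main comparison. Too few counts are argued against by a lower 95% bound of -0.11 for its log2 fold change in the main scaling, above a cutoff of -0.32 set after the data were seen. The scaling stays open for a small fall, since 4 scalings ran from -0.14 with upper quartile scaling, where UFBP1 was called lower (edgeR, adjusted p = 0.0406), to 0.80 with library size alone. UFBP1 RNA from other tissues could hide a fall in fat body, and UFBP1 stood 0.14 above the median of the other 7 UFMylation genes, which decides nothing because no value separates tissues within a library. A fall in protein or at another harvest time was not tested.

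BiP was lower in the siUFBP1 libraries, at a log2 fold change of -1.20. The TMM scaling as the only cause is argued against by the value of -0.40 with library size alone. Fewer fat body transcripts among the counts stay open, because BiP lies below the lower quartile of the fat body markers (-1.13, median -0.68) and within the middle quartiles of the 30 kDa lipoproteins (-1.31 to -0.95). An effect of the siRNA on BiP stays open too, since treatment and tissue makeup change together. So does a difference in the sex of the larvae between the groups, which was not tested.

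With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every other split mixes siNC with siUFBP1 libraries, so the difference between the groups becomes spread within its groups. Few gene and term calls in the other splits follow from this, so the splits decide nothing about chance. The real split was the only 1 of the 10 with counts as large. It gave 4291 higher and 3045 lower genes and 54 terms, and the highest other split gave 0 of each by edgeR and Fisher's exact test. The other splits gave at most 47 genes at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. For lists the real split gave 10 and the highest other split 8.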
